A study of Mus musculus with 2 samples.

How the data were processed

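Hepatic mRNA was measured in apolipoprotein E-deficient male mice on a C57BL/6J/OLA129 background. An age of 2 months is given for both pools. Per the labels' protocols, the livers were washed, frozen and extracted for total RNA, and biotin-labelled cRNA was made for Affymetrix mouse arrays. The labels give 1 array of a control pool, from mice drinking 1% glycerol in water with chow, and 1 array of a squalene pool, from mice whose glycerol drink also delivered squalene at 1 g per kg per day for 10 weeks. The groups were taken from the sample titles, because the growth protocol text is the same for both samples. The number of animals in each pool, the hour of collection and the feeding state at collection are not given in the sources used here.

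The deposited values are probe set intensities on a linear scale, made by the authors with the MAS5 algorithm, per the submitters' processing notes. MAS5 gives 1 signal per probe set, from perfect-match probes less an estimate of stray signal. Both arrays had a 2%-trimmed mean signal of about 200 (200.1 in each), which was seen in the values and is not stated in the sources used here. The software version and scanner settings are not given there either, and detection calls were not used here. Each array held 22690 probe sets, of which 64 were array controls and were left out of the gene counts.

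Gene names came from the platform annotation. A single gene symbol was given for 20380 of the 22626 remaining probe sets, several symbols for 691, and none for 1555. Of those with a single symbol, 20351 were found by Entrez number in the RefSeq gene table, and 0 symbols changed. Probe sets with several symbols or none were counted but not named. Genes without a named probe set were not analysed here. No genome build is named in the sources used here, so no coordinates are given.

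The log2 ratio of the squalene pool over the control pool was taken without a pseudocount. A probe set was called measured when its signal was at or above the array median in at least 1 pool. Each gene was represented by its measured probe set with the highest mean log2 signal. Genes past a log2 ratio of 1.5 in either direction were counted, since the submitters state that limit as their screen. With 1 array per group no test between groups can be made, so no p-values were computed. Their number limits the precision, and the only spread these arrays hold is that between probe sets of the same gene.

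The comparison used 45 gene lists, 6 of them main lists on lipid metabolism and others covering stress, immunity, the clock and markers of other cell types and tissues. For each list the median log2 ratio of its measured members was set against 10000 random lists of the same size matched on mean signal in 10 bins. Its percentile describes these 2 arrays and does not generalise to animals. Members were called higher or lower beyond a log2 ratio of 0.5. The lists, the limit, the filter and the alternatives below were fixed before the data were examined.

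Named genes followed a rule: the 12 highest and 12 lowest genes past the limit, up to 4 members of each described list with the largest ratios, and a fixed set of lipid genes with Apoe, Txndc5 and the array controls. The described lists are the 6 main lists, those with a percentile outside the central 95% of random lists, and, more briefly, markers of other cell types and tissues. The 12 highest and 12 lowest genes with both signals at or above the array median, and some further list members, were added to the named genes after the values were seen. Gene functions are given as background.

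The alternatives were no filter, a filter at the 75th percentile, both pools at or above the median, signals floored at the median, centring, quantile normalization, loess with limma 3.58.1 in R 4.3.3, a pseudocount of 3.0 at the 10th percentile of the signals, and limits of 1.0 and 2.0. Other choices of probe set per gene, probe sets with the plain suffix only, and random lists unmatched on signal were also tried. The other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

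The counting steps were tested on simulated data for this comparison, made from the signals and the spread between probe sets. At a simulated log2 size of 2, 60 of 61 altered genes passed the limit, and at a size of 1 only 2 of 66 did. These altered genes were drawn from those with both signals at or above the median, so recovery of dimmer genes was not tested. Of 7232 unaltered genes, dim ones included, 351 (4.85%) passed the limit. Among 6148 unaltered genes with both signals at or above the median, 10 did (0.163%). A list of 33 genes shifted by 0.3 gave a median of 0.35 and a percentile of 100 among 2000 random lists drawn from 7465 genes.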

Results

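Liver RNA from apolipoprotein E-deficient male mice was compared between a control pool and a pool from mice given squalene, a triterpene intermediate of cholesterol synthesis, at 1 g per kg per day for 10 weeks. Mice lacking apolipoprotein E clear remnant lipoproteins poorly and develop atherosclerosis. Each pool was hybridised to 1 array, so no replicates exist and every ratio below compares these 2 pools. Probe set signals ran from 0.2 to 22342.9 in the control pool, with a median of 39.9, and from 0.1 to 20695.1 in the squalene pool, with a median of 41.4. The 3′/5′ signal ratio of actin was 2.80 in the control and 2.48 in the squalene pool, and that of Gapdh was 0.690 and 0.678. The 18 probe sets of hybridization spike-ins were all lower on the squalene array, with a median log2 ratio of -0.26. Scaling to that median would raise every ratio by 0.26 and turn list medians between -0.26 and 0 positive, but would leave their ranks among random lists as they are. Apoe read 141.0 in the control and 130.6 in the squalene pool (log2 ratio -0.11) on 1 probe set, which cannot check the deletion because the part it targets is not given in the sources used here.

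The comparison asks which liver transcripts differed with squalene. Most genes read alike in both pools. Of 7354 measured genes, 5740 (78.1%) lay within 0.5 of a log2 ratio of 0, and the median was 0.01. Past the log2 limit of 1.5, 89 genes were higher and 98 lower in the squalene pool, or 192 and 188 of 12169 measured probe sets. Of the 89 higher genes, 84 had a control signal below the array median, and of the 98 lower genes, 95 had a squalene signal below it. Between probe sets of the same gene the log2 ratio had an SD of 0.90, 0.33 and 0.18 over tertiles of mean signal, from the dimmest to the brightest. Scaled to all genes, differences between probe sets of the same gene would put 185 genes past the limit, beside the 187 seen. Of 6462 genes with both signals at or above the array median, 5 were higher and 3 lower past the limit.

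**Figure D1:**
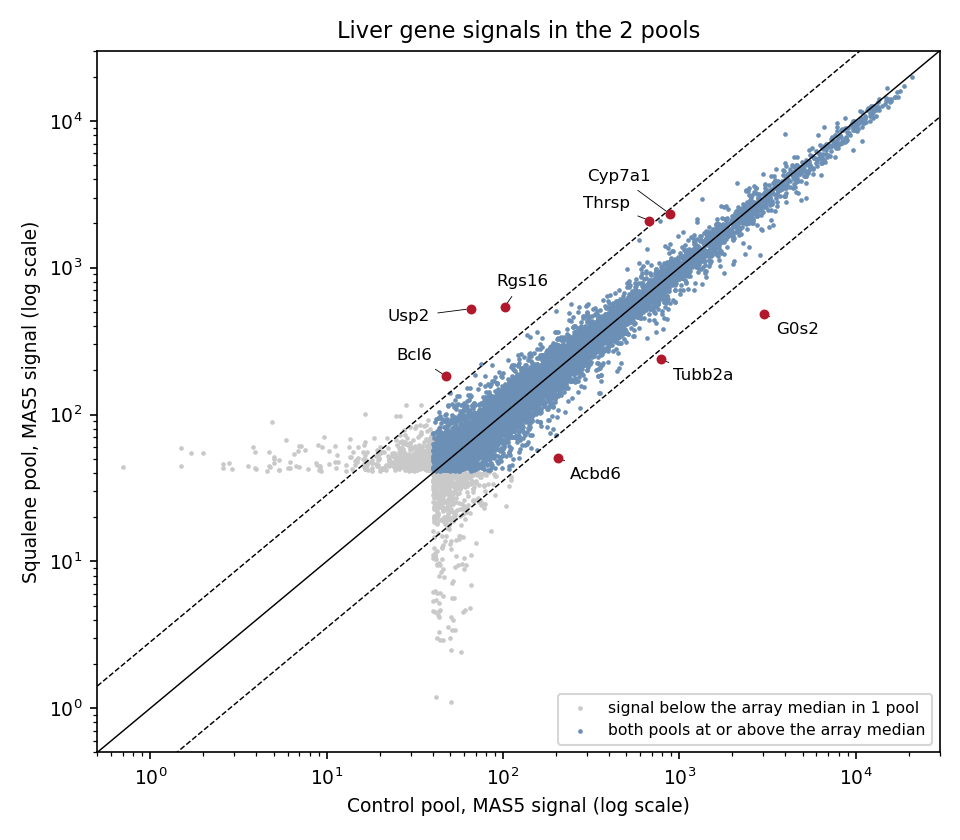
MAS5 signal of each measured gene in the control pool (horizontal, log scale) and the squalene pool (vertical, log scale), 1 array each, with dashed lines at a log2 ratio of 1.5 either way. Grey points lie below the array median in 1 pool and make up most of the 187 genes past the limit, and red points mark Cyp7a1 and the genes with both signals at or above the median that lie past it, except Ppargc1a.

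The genes with the most extreme ratios were those read near the floor of 1 array. The 12 highest were Olfr78, an olfactory receptor, Hcrt, the precursor of the orexin peptides, Gna15, Rhox9, Mcoln3, Arhgef40, Cenpf, Cep152, Lypd8, Dhx38, Srpk2 and Igf2, a fetal growth factor. Their control signals were 0.7 to 4.9 and their squalene signals 42.5 to 88.4, giving log2 ratios from 3.83 for Igf2 to 5.98 for Olfr78. The 12 lowest were Dram1, Macroh2a3, Sv2a, Casp1, Slc6a17, Klrk1, Trav9d-3, Endou, Sfxn3, Ciita, Car9 and Kcnk1, with control signals of 41.9 to 64.7 and squalene signals of 1.1 to 4.8. Their ratios ran from -5.52 for Dram1, a lysosomal membrane protein, to -3.75 for Kcnk1, a potassium channel. All 24 ratios rest on 1 measured probe set each. With no filter, another probe set gave the opposite sign for Olfr78 (-0.56), Mcoln3 (-1.14), Cenpf (-0.61) and Macroh2a3 (1.24). With signals floored at the array median, the 12 highest had log2 ratios of 0.09 to 1.15 and the 12 lowest of -0.65 to -0.02, none past the limit.

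Genes with both signals at or above the array median, called well read here, were also ranked, a set named after the values were seen. Some of them, such as Adgre4, Msr1 and Cic below, still fall in the dimmest tertile of mean signal, where the SD between probe sets was 0.90. Usp2, a deubiquitinase under clock control, was 8.02-fold higher in the squalene pool (65.5 against 525.3), and Rgs16, a regulator of G protein signalling, was 5.30-fold higher (102.3 against 542.5). Next came Bcl6, a transcriptional repressor (log2 ratio 1.93), Thrsp, a lipogenic nuclear protein (1.63), and Ppargc1a, a coactivator of mitochondrial and gluconeogenic genes (1.56). The other probe set of Usp2 (2.92), all 3 of Rgs16 (2.26 to 2.45), both of Thrsp (1.63 and 1.68) and all 5 of Ppargc1a (0.23 to 1.56) lay above 0. Below the limit followed Oxsr1 (1.47), Wdr36 (1.43), Lpin1 (1.42), Dbp (1.39), Cyp7a1 (1.39), the ferritin receptor gene Scara5 (1.34) and Tff3 (1.33). A second probe set of Wdr36 read 0.00.

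At the lower end, G0s2, which encodes an inhibitor of the adipose triglyceride lipase, was 6.19-fold lower in the squalene pool, at 486.7 against 3012.2 on its single probe set. Acbd6 (-2.00) and the tubulin gene Tubb2a (-1.72) were also past the limit, but a second probe set of each read 0.25 and 0.33. Rell1 (-1.46) and the phosphodiesterase gene Pde4b (-1.45) were lower on both of their probe sets. The rest were H2-Eb1 (-1.35), the macrophage genes Adgre4 (-1.33) and Msr1 (-1.33), Id3 (-1.31), Lpl (-1.30), Oxa1l (-1.30) and Cic (-1.30). A second, dimmer probe set of Lpl read 0.60 and that of Oxa1l 0.24. On simulated data, 10 of 6148 unaltered genes with both signals at or above the median passed the limit, beside the 5 higher and 3 lower seen here. The simulated noise could pass it only in the 2 dimmer quintiles of mean signal. In the 3 brighter quintiles 0 were expected from that noise, and 3, 2 and 2 measured genes lay past the limit. That expectation rests on 268, 428 and 777 pairs of probe sets for 1507, 1558 and 1663 genes. So few pairs cannot tell an expectation of 0 from one of a few genes.

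Cholesterol synthesis genes were slightly higher in the squalene pool. Of 17 measured genes of the pathway, 13 lay above 0, with a median log2 ratio of 0.25. Msmo1, a sterol C4 methyl oxidase, read 1047.5 in the control and 1749.7 in the squalene pool (log2 ratio 0.74). Idi1 (0.63) and Fdps (0.58), which make the isoprenoid units that precede squalene, and Sqle, which oxidises squalene itself (0.38), were also above 0, while Mvd was at -0.52. By the band of 0.5, 4 members were higher, 1 was lower and 12 lay between. The median lay at the 99.9th percentile of random lists.

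Other genes of sterol uptake and control, apart from the pathway enzymes, showed a like median of 0.26 over 9 measured members, at percentile 98.9. Lpin1, a phosphatidate phosphatase, was 2.68-fold higher in the squalene pool, and its other probe set gave a log2 ratio of 1.99. Aacs, which activates acetoacetate for lipid synthesis, read 0.72, and Stard4, a sterol carrier, 0.36. Srebf2 itself read 0.42 on its brighter probe set and -0.43 on the other. In total 2 members were higher, 0 lower and 7 between. The percentile was 97.2 with the filter at the 75th percentile of signal, 96.7 with the mean of a gene's probe sets, and 95.6 against random lists unmatched on signal.

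Lipogenic genes went both ways. Thrsp was 3.09-fold higher and Scd1, the main hepatic stearoyl-CoA desaturase, 2.05-fold higher in the squalene pool (3955.6 against 8091.4). Elovl3, which elongates very long chain fatty acids, was 2.36-fold lower (2869.0 against 1215.5), and Scd2 stood at -0.61. Fasn, the fatty acid synthase, read 211.4 and 226.9, a log2 ratio of 0.10. Of 19 measured genes of fatty acid and triglyceride synthesis, 4 were higher, 3 lower and 12 between, with a median of 0.13 at percentile 97.8. That percentile was 96.2 with no filter, 92.4 with the mean of a gene's probe sets, 91.0 against unmatched random lists, and 56.0 with the probe set of smallest ratio, where the median was 0.00.

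Genes of fatty acid oxidation, many of them targets of the nuclear receptor PPAR alpha, lay within the central 95% of random lists as a group. Among the members with the largest ratios, Acot1, an acyl-CoA thioesterase, was 2.13-fold lower, Ehhadh, a peroxisomal oxidation enzyme, 1.59-fold lower, and Acads, the short-chain acyl-CoA dehydrogenase, 1.52-fold lower. Pdk4, a kinase that restrains pyruvate oxidation, read 73.0 and 40.2 (-0.86). Cpt1a, which commits fatty acids to mitochondria, was at 0.17. Of 27 measured members, 0 were higher, 5 lower and 22 between, and 19 lay below 0. Their median was -0.12 at percentile 5.34, and at 1.70 over probe sets with the plain suffix only.

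Genes of the lipid droplet showed no common direction, but held a marked difference in G0s2, described above. Plin2, the main coat protein of hepatic lipid droplets, was 1.72-fold lower in the squalene pool (3233.0 against 1880.5). Plin4 stood at 0.70 with a control signal below the array median, and Lipe, the hormone-sensitive lipase, at 0.42. Of 12 measured members, 1 was higher, 2 were lower and 9 lay between. The median was -0.03 at percentile 41.0, and -0.13 with the filter at the 75th percentile.

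Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 2.62-fold higher in the squalene pool, at 2320.5 against 885.7. Its other probe set gave a log2 ratio of 1.38. Cyp39a1, an oxysterol hydroxylase, stood at 0.88 and Akr1d1, a steroid reductase of the pathway, at 0.65. Nr0b2, a repressor of Cyp7a1, was at 0.49. Of 17 measured genes of bile acid synthesis, 3 were higher, 0 lower and 14 between, with a median of 0.05 at percentile 93.5. The median was 0.11 after quantile normalization, 0.14 with the mean of a gene's probe sets and 0.20 over plain-suffix probe sets, and the last 2 settings put it at percentiles 99.7 and 99.9.

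Apolipoproteins and proteins that handle lipoproteins were slightly lower as a group than random lists, by less than the offset of the spike-ins. Lpl, which hydrolyses lipoprotein triglycerides, was 2.46-fold lower in the squalene pool on its brighter probe set, and Apobec1, which edits apolipoprotein B mRNA, 1.61-fold lower. Tm6sf2 stood at -0.42 and the paraoxonase gene Pon3 at -0.35. The abundant transcripts differed little, with Apoa1 at -0.06 and Apob at 0.07. Of 22 measured members, 0 were higher, 2 lower and 20 between, and 17 lay below 0, with a median of -0.17 at percentile 0.74. After quantile normalization or loess the median was -0.08, at percentiles 5.07 and 5.57, and against unmatched random lists the percentile was 2.62.

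Circadian genes stood farthest above random lists. Besides Usp2, the PAR bZIP clock output genes Dbp (2.63-fold higher) and Hlf (1.04) and the period genes Per3 (16.5 against 100.6) and Per2 (28.3 against 116.4) were higher in the squalene pool, while Per1 was lower (59.9 against 36.9, log2 ratio -0.70). Arntl, whose protein BMAL1 drives the clock with CLOCK, read 66.2 in the control and 11 in the squalene pool, a log2 ratio of -2.59, or -0.68 with signals floored at the array median. Clock stood at -0.31. Of 19 measured members, 11 were higher, 2 lower and 6 between. Their median was 0.70 at percentile 100, and 0.70 over the 15 members with both signals at or above the array median. The signals of Per2 and Per3 in the control pool and of Arntl and Per1 in the squalene pool lay below the median.

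**Figure D2:**
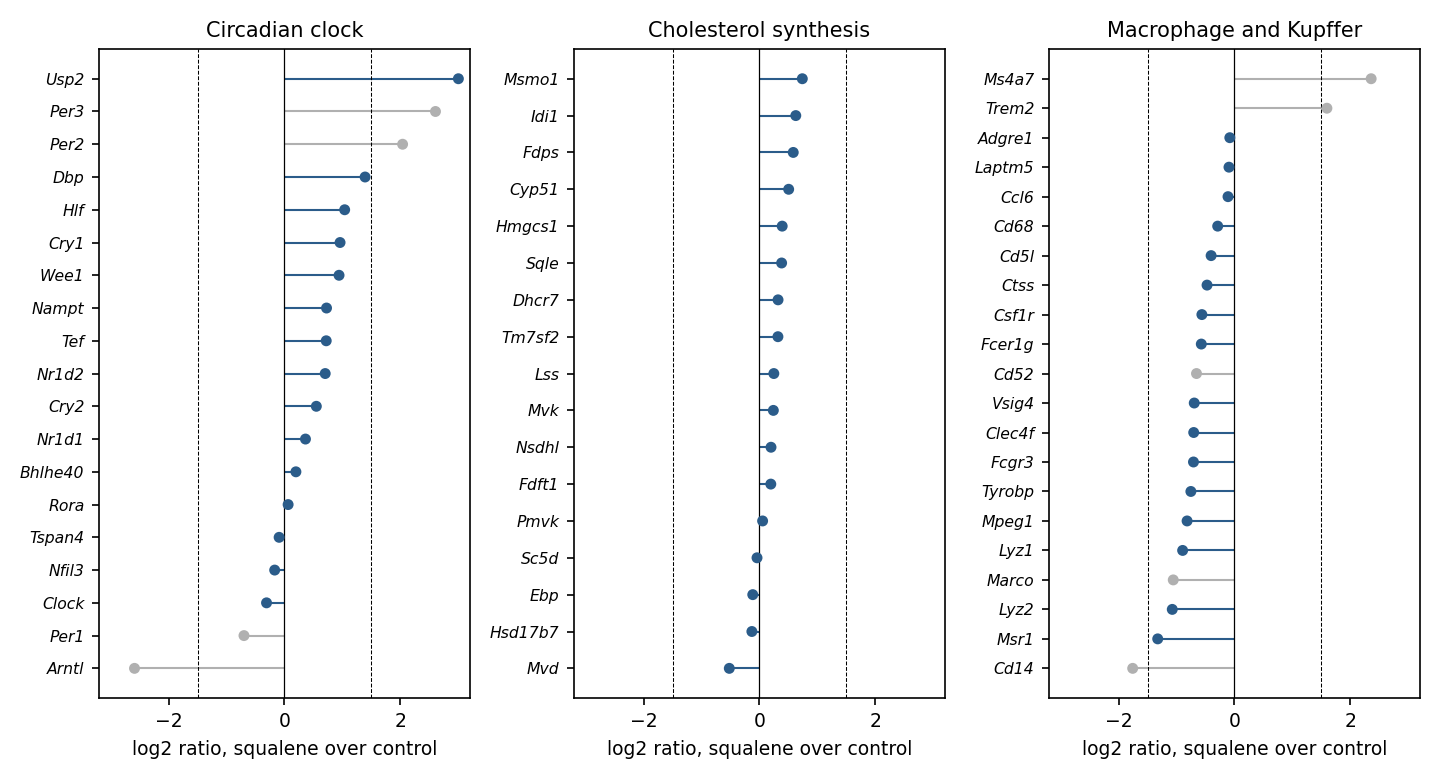
Log2 ratio of squalene over control pool (horizontal) for each measured member of 3 gene lists, 1 array per pool, with dashed lines at 1.5 either way and grey where a signal lay below the array median in 1 pool. Most clock genes lie right of 0 and Arntl lies at -2.59, 13 of 17 cholesterol synthesis genes lie right of 0, and 19 of 21 macrophage markers lie left of it.

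Macrophage and antigen presentation genes were lower in the squalene pool. Of 21 measured macrophage and Kupffer cell markers, 19 lay below 0, with a median of -0.66 at percentile 0.00. Lyz2, a macrophage lysozyme, stood at -1.07, the scavenger receptor Msr1 at -1.33, the Kupffer cell lectin Clec4f at -0.70, Vsig4 at -0.69 and the receptor Csf1r at -0.56, while Adgre1, which encodes F4/80, was at -0.08. By the band, 13 were lower, 2 higher and 6 between. Ms4a7 (8.8 against 45.2) and Trem2 (16.5 against 49.9) were the 2 higher, both dim in the control pool, and Cd14 (-1.76) was dim in the squalene pool. All 16 members with both signals at or above the median lay below 0, with a median of -0.63.

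Antigen presentation genes of MHC class I and II had a median of -0.70 at percentile 0.00, with 12 of 13 measured members below 0. The median was -0.50 over the 10 members well read in both pools, and -0.31 both with floored signals and with the filter at the 75th percentile. The class II genes H2-Eb1 (2.55-fold lower), H2-DMa (-1.09) and Cd74, the invariant chain (468.3 against 223.3), and their regulator Ciita (-3.81) were among the 8 called lower, with 0 higher and 5 between. H2-DMa and Ciita were dim in the squalene pool. The class I genes H2-K1 (-0.31) and H2-D1 (-0.16) differed less. Interferon-stimulated genes had a median of -0.21 over 20 measured members, at percentile 2.02, with 7 lower, 0 higher and 13 between. That median is smaller in size than the offset of the spike-ins, so scaling to them would turn it positive and keep only its rank. Bst2 (-0.93), Oas1a (-0.81), the peptide transporter Tap1 (-0.77, also in the preceding list) and Ifit3 (-1.32, dim in the squalene pool) were the most extreme. With the filter at the 75th percentile their percentile was 4.73.

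Lymphocyte markers were mostly too dim to place. Of 6 measured members 3 were lower, Klrk1 (-3.98), Ccl5 (-2.44) and Igha (-1.56), each with a squalene signal below the array median, 1 was higher and 2 lay between. Ighm stood at 0.71 on its brightest probe set and at -3.02 and -2.01 on the others. The list's median was -0.91 at percentile 0.47. It was 0.13 with no filter, 0.13 over the 3 members well read in both pools, and -0.11 with floored signals.

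Chaperones of the endoplasmic reticulum and ribosomal proteins were slightly lower as groups than random lists, again by less than the offset of the spike-ins. Scaling to the spike-ins would thus keep only their rank. After quantile normalization and loess the chaperone list had a median of -0.12 in both, at percentiles 1.99 and 1.52. The ribosomal list then had -0.09 and -0.11, at percentiles 1.80 and 0.90. Of 28 measured protein disulfide isomerases and chaperones, 24 lay below 0, with 0 higher, 2 lower and 26 between and a median of -0.16 at percentile 0.41. Creld2 (-0.61), Pdia4 (-0.51), Pdia3 (-0.42) and Sdf2l1 (-0.41) were the most extreme, and Txndc5, a thioredoxin-domain protein of that compartment, stood at 0.01 on its brighter probe set and -0.28 on the other. The list's percentile was 9.23 with the filter at the 75th percentile and 2.58 with the probe set of smallest ratio. Of 22 cytosolic ribosomal proteins, 19 lay below 0, with 0 higher, 1 lower and 21 between and a median of -0.17 at percentile 0.41. Rpl22 was at -0.72 on 1 probe set and -0.06 on the other, and Rpl35 (-0.31), Rps19 (-0.30) and Rps18 (-0.28) followed. That percentile was 20.3 over the 6 members with a plain-suffix probe set, and 2.52 with the probe set of smallest ratio.

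Markers of other cell types and tissues were otherwise near 0 or few. Endothelial markers had a median of -0.03 over 15 measured genes (percentile 35.6), but -0.32 (0.51) over the 6 that passed the filter at the 75th percentile. Hepatocyte markers had a median of -0.06 over 18 (46.5), which was 0.03 after quantile normalization and 0.06 after loess. Stellate cell and matrix genes had -0.14 over 20 (4.72), and 0.01 both with the filter at the 75th percentile and over plain-suffix probe sets. Medians were -0.39 over 4 neutrophil markers (18.8), -0.30 over 5 blood cell markers (8.28; 0.10 over plain-suffix probe sets), -0.38 over 4 exocrine pancreas markers (17.5) and -0.17 over 3 adipose markers (27.4; 0.21 with the mean of a gene's probe sets). The exocrine pancreas list had -0.28 at percentile 2.44 with floored signals, and -0.03 at 41.3 over 15 members with no filter. The 3 measured intestine and gallbladder markers, all of them read in liver here, went both ways, with Tff3 at 1.33, Aqp8 at -0.82 and Fabp2 at -0.44, a median of -0.44 (percentile 0.89) and a mean of 0.02. With unmatched random lists that percentile was 4.37. Of the cholangiocyte list only Onecut1 was measured (59.0 against 4.5, dim in the squalene pool), and 0 muscle markers were. Across the 43 lists with 3 or more measured members, 12 lay outside the central 95% of random lists. By chance 2.15 would, if members of a list were as unrelated as the genes of random lists. Whether members vary together between animals cannot be seen with 1 array per pool, so no excess over chance is read from this.

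**Figure D3:**
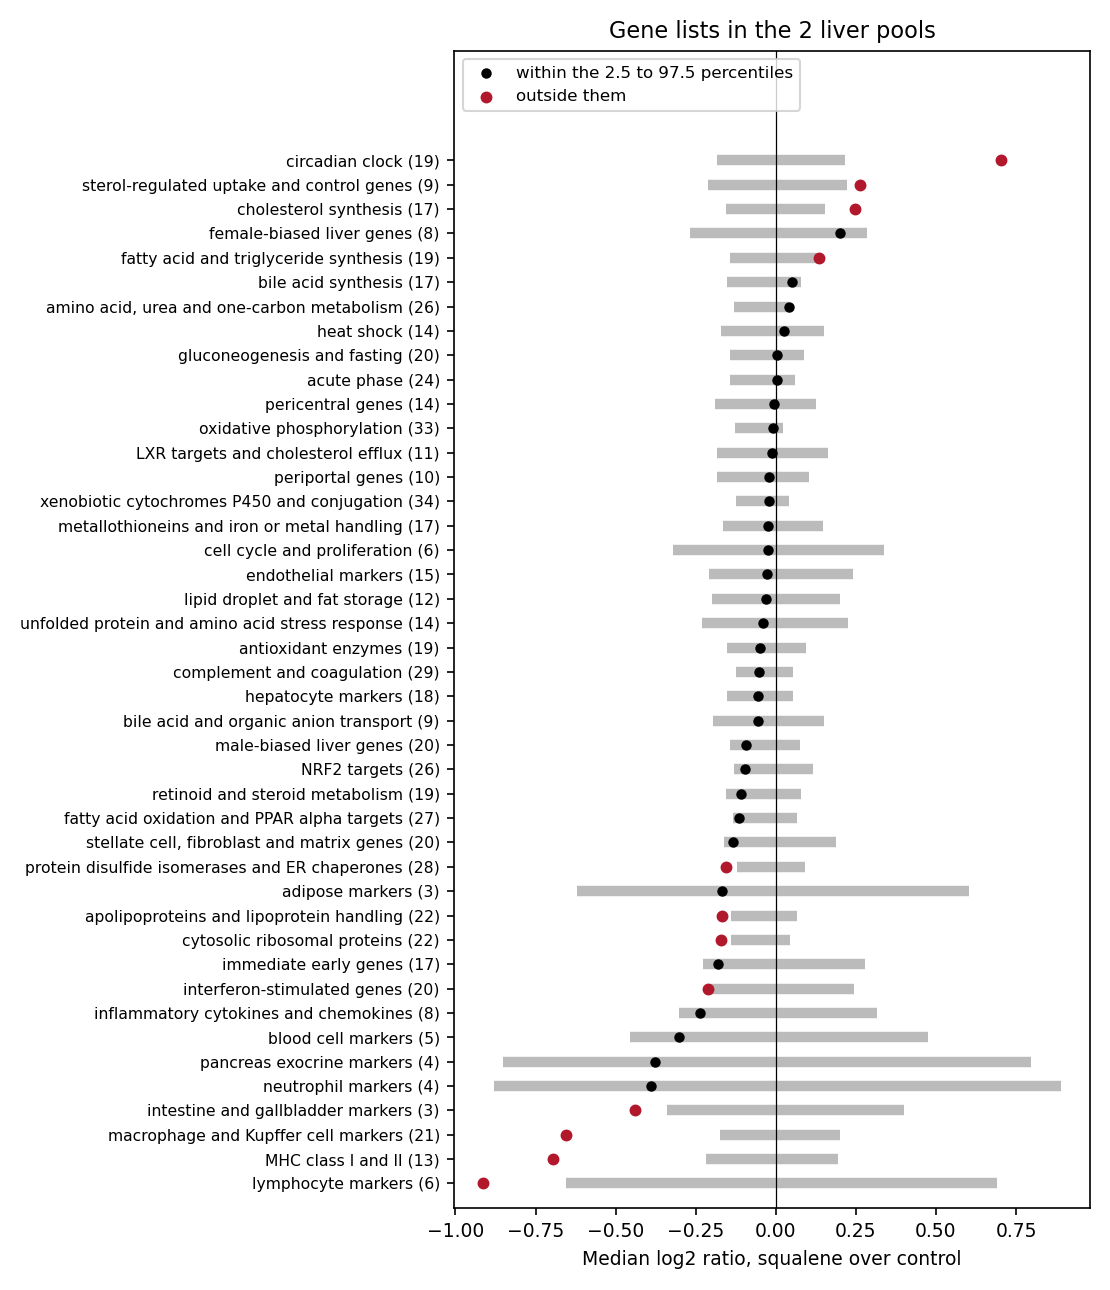
Median log2 ratio of squalene over control pool (horizontal) of each gene list, with the number of measured members in brackets and grey bars for the central 95% of 10000 random lists matched on signal. The 12 red points lie outside the bars, from the lymphocyte list at -0.91 to the clock list at 0.70.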

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

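The counts past the limit depended on how dim signals were treated. They were 974 higher and 905 lower genes with no filter (2097 and 1860 probe sets), 5 and 3 with the filter at the 75th percentile, 5 and 3 with both pools at or above the median, and 7 and 3 with floored signals, against 89 and 98. The share of higher genes was thus 62.5% and 70.0% in the last settings, on few genes. Limits of 1.0 and 2.0 gave 231 and 223 or 58 and 61, by their construction. Centring, quantile normalization and loess moved the median of all genes by at most 0.02, and left 88 genes higher and 102, 109 and 108 lower. Cholesterol synthesis, clock, macrophage and MHC lists kept their side of the percentile bounds under 11 of 11 alternatives. Their medians ran from 0.20 to 0.35, 0.36 to 0.71, -0.70 to -0.57 and -1.09 to -0.31, the first at 0.35 with the filter at the 75th percentile. Other main lists moved. Under that filter the lipid droplet list had a median of -0.13. The bile acid list had 0.11 after quantile normalization, 0.14 with the mean of a gene's probe sets and 0.20 with plain-suffix probe sets, and the fatty acid synthesis list 0.00 with the probe set of smallest ratio. The cause was not tested. Lymphocyte markers turned from -0.91 to 0.13 both with no filter and with both pools at or above the median. No filter brought in other members, 23 in all, and the second setting left 3 of the 6. That list and 5 other small lists gave no value under some settings that left fewer than 3 members, such as the filter at the 75th percentile. With no filter another probe set stood for Olfr78 (-0.56), Mcoln3 (-1.14), Cenpf (-0.61) and Macroh2a3 (1.24), against the sign given above. Acbd6 (0.25) and Tubb2a (0.33) turned with the probe set of smallest ratio and with plain-suffix probe sets, which also took another probe set. Over all lists and named genes, 385 list medians and 925 gene ratios stayed within the spread, and 73 and 72 moved beyond it. Counting every sign change, small ones near 0 included, 48 medians of 21 lists and 16 ratios of 12 genes turned. Beyond the lymphocyte list, those that moved past the spread and turned were 23 medians of 13 lists, all within the percentile bounds at first, such as the immediate early list from -0.18 to 0.12 with the filter at the 75th percentile. Random lists unmatched on signal ended the calls of 4 lists, at percentiles 95.6, 91.0, 2.62 and 4.37. No paired analysis was possible because each group has 1 array, which also rules out leaving arrays out in turn. Signals near the floor limit what can be read: below a mean signal of 82.1 the SD between probe sets was 0.90.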

Other observations

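The gene lists and their comparison with random lists were planned, but the genes named here and the tests of the 3 patterns at the end were chosen after the results were seen. Glucose and fasting genes split. Ppargc1a (1.56), the transcription factors Foxo3 (0.87) and Foxo1 (0.60) and Gys2, the liver glycogen synthase (0.74), were higher in the squalene pool. G6pc, the catalytic subunit of glucose-6-phosphatase, was 1.74-fold lower (3384.3 against 1950.1), Igfbp1 1.57-fold lower and Cdkn1a 2.16-fold lower. The list of 20 measured genes had a median of 0.00 at percentile 72.8, with 5 higher and 4 lower, but 0.22 at percentile 99.9 over plain-suffix probe sets and 0.10 at 95.9 after quantile normalization. The unfolded protein response gene Herpud1 was 1.79-fold higher (2118.5 against 3796.8) although the chaperone list ranked low among random lists. Oxidative phosphorylation showed little difference, since all 33 measured members lay within 0.5 and the median was -0.01 at percentile 87.3 (0.07 after quantile normalization).

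Of 34 measured xenobiotic genes, 7 were higher, 2 lower and 25 between. Cyp2b10, a target of the receptor CAR, was 1.95-fold lower in the squalene pool (1782.2 against 913.1), while Cyp3a13 (0.75) and Cyp2c38 (0.74) were higher, and the list had a median of -0.02 at percentile 72.2 (0.06 after quantile normalization). Among 26 targets of the oxidative stress factor NRF2, Gclc, which limits glutathione synthesis, was 1.57-fold lower (2305.7 against 1466.9) and Nqo1 1.63-fold higher from 44.6, with a median of -0.09 at percentile 8.44 (-0.17 at percentile 0.36 with no filter, 0.01 at 69.7 with the filter at the 75th percentile). The complement genes C1qa (-0.68) and C1qb (-0.68), made largely by macrophages, were lower beside the macrophage markers. Of 20 stellate and matrix genes, 5 were lower and 0 higher by the band of 0.5, namely Acta2 (2.01-fold lower), Lum (-0.88), Col1a2 (-0.71), Pdgfrb (-0.70) and Col3a1 (-0.70), while 8 lay above 0, among them Col4a2 (0.45) and Col5a2 (0.44). Genes with higher expression in females split 4 above and 4 below 0, from Lpl (-1.30) to Cyp17a1 (1.91, dim in the control pool). Their median was 0.20 at percentile 92.1, but -0.18 over members well read in both pools and -0.25 with the filter at the 75th percentile. It was 0.55 at percentile 99.8 with the probe set of smallest ratio and 0.85 at 99.99 over plain-suffix probe sets, so no direction is given.

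Clock genes differed between the pools by more than scaling or dim signals account for. Under centring, quantile normalization and loess the lowest list median was 0.68, and over members well read in both pools it was 0.70, beyond the upper bound of the central 95% of random lists, 0.20 in both cases. A candidate explanation is that the livers of the pools were at different phases of the clock. An output arm of 9 genes, in which Per1 was counted, had a median of 1.04, with 8 above 0 and Per1 below it. The activators Arntl and Clock both lay below 0. The gap between the medians was 2.49, or 1.53 with floored signals. With floored signals the 2 activators had a median of -0.49 against an SD of 0.32 for random pairs. The arms hold 11 genes, and of all 19 measured clock members 14 lay above 0 and 5 below. Whether such a phase difference came from the hour of collection, from feeding or from squalene stays open and untested with 1 pool per group. Cyp7a1, Lpin1 and Thrsp, whose mRNA cycles daily in liver, could carry the phase difference too. The other genes and lists described above were not examined for it.

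Macrophage and MHC class II genes were lower together. Noise of dim probe sets would not leave the 16 macrophage markers well read in both pools at a median of -0.63, against a lower random bound of -0.16, and was not tested for class II genes alone, though the 10 well-read MHC genes had a median of -0.50 at percentile 0.00. A lower share of all non-parenchymal cells is argued against as the whole cause by well-read endothelial markers, whose median of -0.05 over 14 members lay 0.58 above it, but with the filter at the 75th percentile the gap was 0.37 (SD 0.16), with 6 endothelial genes at -0.32, and 5 stellate and matrix genes were lower with 0 higher, so a part stays open. A strain variant in the H2 region of chromosome 17 is not the whole cause of the joint pattern. On other chromosomes 17 of 17 well-read members lay below 0 with a median of -0.69 (21 of 22 with dim members, Ms4a7 being above). Nearly all of those are the macrophage markers already counted above, so they say little on class II genes. Such a variant stays open for the class II genes on chromosome 17, H2-Aa, H2-Ab1, H2-Eb1, H2-DMa and H2-DMb2, all below 0. With the class I and peptide-loading genes and the macrophage markers Adgre1 and Trem2, 12 measured members lie on the chromosome, of which 10 were below 0 and Trem2 (1.60, dim in the control pool) and Tapbp (0.09) above. As a hypothesis, the squalene pool may have held fewer macrophages or less activated ones, which these arrays do not separate, and animals that differed for reasons other than squalene stay open.

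Most genes past the limit were dim in 1 pool. Differences between probe sets of the same gene, scaled by brightness, give 185 expected genes past the limit against 187 seen, which is consistent with noise as the source of nearly all of them. In the dimmest quintile of genes 175.0 were expected and 174 seen. In the 3 brighter quintiles 0 were expected and 3, 2 and 2 seen, but with 268, 428 and 777 pairs these do not differ clearly. The simulation drew on the same differences but gave 351 of 7232 unaltered genes past the limit, and 10 of 6148 well read in both pools, so the expected number is uncertain. Its noise, too, could pass the limit only in the 2 dimmer quintiles.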
